A study of Mus musculus with 7 samples.

How the data were processed

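Bone marrow of young and old mice was stained and sorted for cells that lacked lineage markers and Sca1 and carried cKit, CD150 and CD41, the phenotype of megakaryocyte progenitors, which are the bone marrow cells committed to making megakaryocytes and platelets. The labels list 7 RNA-seq libraries: 3 from young mice aged 3 months and 4 from old mice, given as 18 to 20 months in one label and as the upper of those ages in another. The mice carried Flt3-Cre and the mTmG reporter, in which a cell changes from red (Tomato) to green (GFP) fluorescence once it or an ancestor has expressed the recombinase. Per the labels' protocols, sorted fractions were Tomato-positive or GFP-positive. The titles of the 3 young libraries share 1 prefix, and those of the old libraries carry 2 prefixes with 2 libraries each. What the prefixes stand for is not stated, so libraries were grouped by the age label alone. If the prefixes mark the sorted reporter fraction, which is not given in the sources used here, part of any difference by age may be a difference between fractions. One old library is labelled as strain C57BL/7, the others as C57BL/6. No label says whether the libraries came from separate mice, so the spread behind the p-values may be technical.

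Total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. Bowtie2, STAR, DESeq and the mouse build mm10 are named in the submitters' processing notes, with no versions, roles or order. Counting method, strand setting and annotation version are not given in the sources used here. The authors deposited a single table of their own comparison. Its columns give, for each gene model, the mean normalized count of the young and of the old group, which is a scaled signal with no value per library, a mean over 14 samples, the log2 fold change of old over young with its standard error, the Wald test score, the p-value and the adjusted p-value, per the file headers. The log2 fold change is named as a maximum a posteriori estimate in the file headers. It differed from the log2 ratio of the 2 deposited means by less than 0.1 in 98.5% of the 757 gene models with both means above 0, so the deposited values were read as not shrunken. The deposited test score equals the fold change divided by its standard error.

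The deposited table holds 769 gene models with adjusted p up to 0.0993, so it was selected at 0.1. From the deposited p-values and adjusted p-values, the authors' Benjamini-Hochberg adjustment covered 11778 gene models. Genes absent from the table have no value here, and a count at an unadjusted p cannot be made. The old group's column name matches no single title. With 3 young libraries, the 14-sample mean leaves room for at most 4.08 libraries behind the old mean, which allows all 4 and does not exclude fewer. The 14 samples include some outside this series, and the authors' estimate of spread may rest on them too. The total count per library is not given in the sources used here, so the depth of each library is unknown and no counting interval or detection floor was computed. The precision of each value is the authors' standard error.

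No model was fitted across libraries, since the deposited values are group means. For the same reason the planned count models, other normalizations, pseudocounts, omission of single libraries, separate fits to the 2 kinds of old title and regrouping of the libraries could not be run. The comparison of list members with uncalled genes could not be run because gene models above the adjusted p limit of 0.1 have no values. Gene models at the authors' adjusted p under 0.05 are called higher or lower in old. Before the data were examined, 28 gene lists were fixed: sort gate antigens, megakaryocyte and platelet genes, megakaryocyte transcription factors, haematopoietic stem cell (HSC) and multipotency genes, an aged HSC signature, erythroid, granulocyte and monocyte, lymphoid and plasma cell, mast cell, basophil and eosinophil, stroma and endothelium, interferon response, antigen presentation, inflammatory signalling, immediate early and dissociation stress, unfolded protein and integrated stress response, p53 and senescence, cell cycle, glycolysis, lysosome and autophagy, lipid and sterol metabolism, redox and metallothionein, chromatin and epigenetic regulators, sex-linked genes, ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, histones, and integrins and extracellular matrix. They were compiled from general knowledge, and the aged HSC signature holds genes widely described as higher in aged HSCs.

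Each list with at least 5 called members was tested for direction by Fisher's exact test, two-sided, which set higher against lower calls in the list against all other called gene models. The p-values were adjusted by Benjamini-Hochberg over the 7 lists tested. Since 62.0% of all calls were higher, a list with all of its 5 calls higher could not pass, and one with all of its 7 calls higher had p = 0.0479 by Fisher's exact test before adjustment. Genes are not independent replicates, so these tests describe the calls of this comparison. In 100 simulated tables of 487 gene models with 10 lists of 10 genes each, at least 1 list passed in 1.0% of tables with random directions, and a list with all 10 genes lower passed in 100.0% of tables, which the smaller share of lower calls makes near certain. A list with all 10 genes higher passed in 0.0% of tables, and one with 8 of 10 genes in either direction in 0.0%. The share of higher calls and the adjustment over 10 lists largely set the first of these outcomes in advance. The test thus has little power for mixed lists, and for a short list of higher genes when no other list passes. In the data, the aged HSC list with 10 of 10 calls higher had p = 0.0160 by Fisher's exact test before adjustment. It passed over 7 lists because other lists had smaller p-values. A bound on enrichment was added after the data were seen: a one-sided hypergeometric test that counts every annotated member of a list as tested among the 11778 gene models. This overstates the calls chance would give if all gene models were equally likely to be called. The chance of a call may differ with expression level, so the bound is not a strict upper limit. Where a count is given as adjusted over the list alone, members absent from the table were given a p of 1.

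Genes named in the text follow a rule fixed before the data were examined. Per direction it takes the 10 smallest adjusted p and the 5 largest fold changes at a mean normalized count of at least 50, among called genes whose symbol is not a Gm number, a Rik clone or an accession starting with AC, BC or AI; other accession-like symbols, such as AW112010, were kept. It adds up to 4 called members of every list by adjusted p, and all listed members of the sort gate and sex-linked lists. The mean of the 2 group means was used for the count minimum, because the 14-sample mean includes other samples. Genes named outside the rule are marked where they appear. Gene positions are from GENCODE M21 on GRCm38, the assembly of which mm10 is the browser name. It matched 714 of the 764 symbols in the table. Alternatives tried were adjusted p limits of 0.01 and 0.1, a log2 fold change of at least 1, mean counts of at least 10 and 50, leaving out predicted genes, and a permutation test of list means with 100000 resamples. Added after the data were seen were a minimum on the 14-sample mean, removal of gene models with a standard error over 1, removal of the granulocyte and monocyte list, merging of neighbouring gene models, and recentring of all fold changes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.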

Results

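The transcriptome of sorted megakaryocyte progenitors was compared between 3 libraries from young mice aged 3 months and 4 libraries from old mice aged 18 to 20 months, to ask which genes these cells express differently in old age. The values are the authors' group means of normalized counts and their fold changes from the deposited table. Each log2 fold change (old over young) is given with the authors' standard error (SE), and adjusted p-values are the authors' DESeq values. The means carry no replicate spread of their own, and the depth of the libraries is unknown. The young libraries carry 1 kind of title and the old libraries 2, so age is partly confounded with the kind of title.

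The libraries of old sorted cells had higher levels of 26 granulocyte and monocyte genes, of Cd74 and the MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1, of 10 genes described as higher in aged haematopoietic stem cells (HSCs) and of 11 interferon-induced genes. They had lower levels of 185 gene models, led by Mtif3, Gtf3a and Prodh. Of 11778 gene models in the authors' adjustment, 487 (4.13%) passed an adjusted p under 0.05 in the authors' deposited table. Of these, 302 (62.0%) were higher in old and 185 were lower. Another 282 gene models were listed with an adjusted p between 0.05 and 0.1.

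The 2 directions differed in size and in level. Higher calls had a median log2 fold change of 2.37 (quartiles 1.54 and 3.68) and a median young mean of 29.1 normalized counts in the authors' deposited table. Lower calls in the authors' deposited table had a median log2 fold change of -0.72 (quartiles -0.83 and -0.57) and a median young mean of 2195. A log2 fold change of at least 1 in size was reached by 270 higher and 16 lower calls. The median SE was 0.62 for the higher and 0.19 for the lower calls in the authors' deposited table. With all fold changes recentred by 0.39 on the log2 scale, the single shift that best fitted the lower calls, 423 listed gene models passed as higher and 5 as lower (98.8% higher). That shift was taken from the lower calls themselves and gene models outside the table could not enter, so this split moves by construction and does not show which scaling is right.

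**Figure D1:**
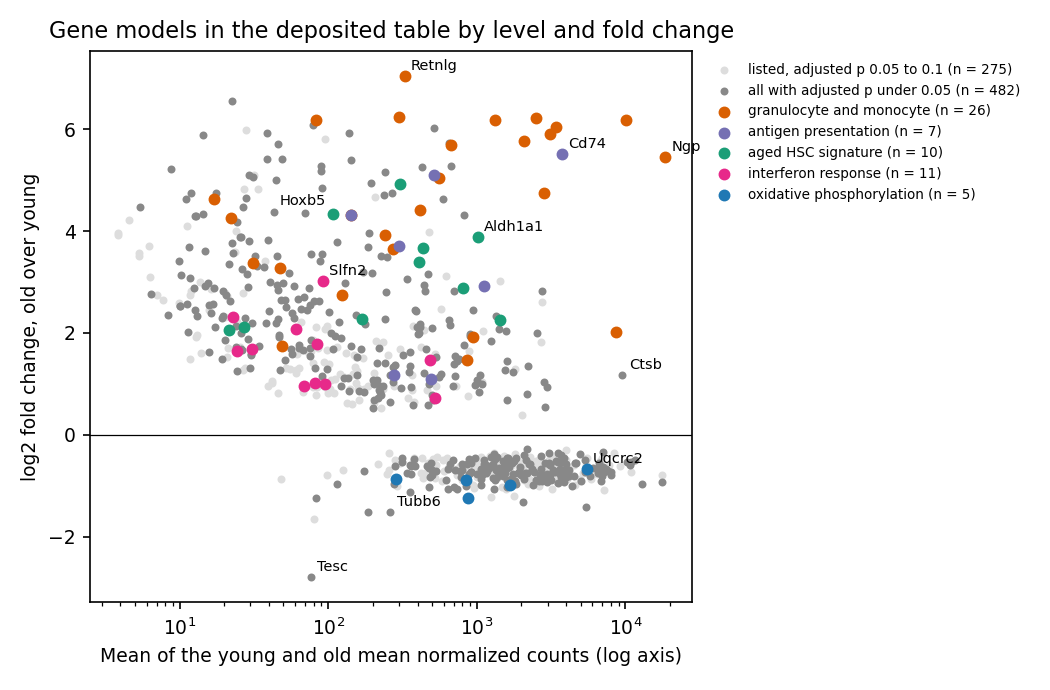
Log2 fold change of old over young (y axis) against the mean of the 2 group means of normalized counts (x axis, log scale), with 1 point per gene model; 12 models with a mean listed at 0 are left out, and a gene in several lists takes the colour drawn last. The higher calls spread up to 7.05 for Retnlg, while the lower calls have a median of -0.72 and reach -2.80 for Tesc.

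Cd74 and 3 MHC class II genes were higher in old. Cd74, the invariant chain that guides MHC class II assembly (chromosome 18, 60803848 to 60812652, plus strand), went from a mean of 161 to 7346 normalized counts, a 45.5-fold rise (log2 fold change 5.51, SE 0.53, adjusted p = 4.55e-21), the smallest adjusted p in the authors' deposited table. H2-Aa (chromosome 17, 34282744 to 34287823), an MHC class II alpha chain, rose from 29.3 to 1008 (5.10, SE 0.65) in the authors' deposited table. The beta chains H2-Eb1 (3.71, SE 0.55) and H2-Ab1 (2.92, SE 0.47) also rose in the authors' deposited table. All 7 called genes of the antigen presentation list, which has 27 annotated members, were higher in old. They include the class I genes H2-M3 (1.17, SE 0.33) and H2-T22 (1.09, SE 0.35) and the lysosomal protease Ctss (4.31, SE 1.06), whose values in the authors' deposited table were seen before they were chosen. Adjusted over the list alone, 7 members passed. With all 7 calls already higher, Fisher's exact test of direction gave the smallest p that 7 calls allow (p = 0.0479, adjusted p = 0.0559), so missing the threshold says little about the list. The bound on enrichment, an exact hypergeometric test, passed (adjusted p = 0.00114). The direction of the same 7 calls passed at a mean count of at least 50 (Fisher's exact test, adjusted p = 0.0265). That setting left 198 higher and 185 lower calls in all, against 302 and 185. The smaller p thus came from the other calls and adds no evidence about the list. A permutation test of the list's mean log2 fold change passed (adjusted p = 0.0311). Fisher's exact test did not pass at an adjusted p limit of 0.01 (adjusted p = 0.59) or among calls with a log2 fold change of at least 1. The 5 and 7 calls of the list left there were all higher. Of all calls left, 77.2% and 94.4% were higher, so a list of that size could not pass. Granulocyte and monocyte markers were also higher in these old libraries, by a median log2 fold change of 4.68 over 26 called genes in the authors' deposited table.

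All called genes of the aged HSC list were higher in the old libraries. Its 10 called members, of 71 annotated, rose (Fisher's exact test, p = 0.0160, adjusted p = 0.0279), with a median log2 fold change of 3.14 in the authors' deposited table. The list passed the adjustment because other lists had smaller p-values, unlike the simulated list with all 10 genes higher. The direction did not pass at an adjusted p limit of 0.01 (Fisher's exact test, adjusted p = 0.59) or among calls with a log2 fold change of at least 1 (adjusted p = 1.0), where most calls left were higher. Adjusted over the list alone, 14 members passed, all listed as higher, and the bound on enrichment, an exact hypergeometric test, passed (adjusted p = 0.00558). Aldh1a1, a retinaldehyde dehydrogenase, rose 14.8-fold from 129 to 1909 normalized counts (3.89, SE 0.49, adjusted p = 6.06e-12) in the authors' deposited table. Plscr2, a phospholipid scramblase, rose from 19.3 to 586 (4.93, SE 0.79) in the authors' deposited table. Casp12, a caspase of the inflammatory subfamily (4.33, SE 0.78), and Mmp14, a membrane-bound matrix metalloproteinase (2.27, SE 0.43), also rose in the authors' deposited table. Of the 10 genes, 4 stand in another list as well, and the old libraries with these higher levels also had the 26 higher granulocyte and monocyte calls.

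The 2 megakaryocyte lists had 1 call each, and the stem cell list had 4. In the HSC and multipotency list 4 of 42 genes were called, all higher: the homeobox factor Hoxb5 rose from 3.97 to 82.0 normalized counts (4.38, SE 0.95), Krt18 by 2.26 (SE 0.63), Pdzk1ip1 by 1.34 (SE 0.37) and Ly6a by 2.08 (SE 0.67) in the authors' deposited table. Ly6a encodes Sca1, against which the cells were gated. It went from 23.5 to 98.8 normalized counts (adjusted p = 0.0499) and was the only called sort gate gene in the authors' deposited table. Slamf1, which encodes the gate marker CD150, was listed at 79.3 in young and 228 in old without passing (1.54, SE 0.55, adjusted p = 0.0856) in the authors' deposited table. In the megakaryocyte and platelet list only Selp, the platelet adhesion receptor P-selectin, was called among 58 annotated genes (496 to 2358, 2.25, SE 0.68, adjusted p = 0.0304), and adjusted over the list alone no member of the authors' deposited table passed. Among megakaryocyte transcription factors, only the ETS factor Erg was called (1.76, SE 0.41) of 26 annotated genes in the authors' deposited table. These lists had fewer than 5 called members and were not tested for direction. For the HSC and multipotency list, 1.72 calls were due by chance under the bound on enrichment, an exact hypergeometric test, which did not pass (adjusted p = 0.287). For the megakaryocyte and platelet list 2.38 calls were due under it, and for the megakaryocyte transcription factors 1.07. Their counts of 1 are thus near chance and do not show that these genes were spared.

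Among interferon-induced genes 11 of 91 were called, and among inflammatory signalling genes 7 of 56, all of them higher in old. All 11 called genes of the interferon list rose (Fisher's exact test, adjusted p = 0.0197), by a median log2 fold change of 1.64 in the authors' deposited table. Slfn2, a Schlafen family gene, rose from 20.1 to 163 normalized counts (3.02, SE 0.45, adjusted p = 2.09e-08) in the authors' deposited table. The interferon-inducible GTPases Igtp (1.46, SE 0.34), Iigp1 (2.30, SE 0.58) and Gbp2 (0.99, SE 0.26) followed with smaller changes in the authors' deposited table. Igtp overlaps in exons with Irgm2, another called member that was chosen after its values were seen, so these calls may share reads. Adjusted over the list alone, 16 members passed, and the bound on enrichment, an exact hypergeometric test, passed (adjusted p = 0.00841). The rise of this list was below that of the other higher calls, and a permutation test of its mean log2 fold change against all other calls did not pass (adjusted p = 0.82). Its direction also did not pass at an adjusted p limit of 0.01 (Fisher's exact test, adjusted p = 0.59) or among calls with a log2 fold change of at least 1 (adjusted p = 1.0). The 5 and 8 calls of the list left there were all higher. Of all calls left, 77.2% and 94.4% were higher, so a list of that size could not pass. All 7 called inflammatory signalling genes rose, with the NF-kB inhibitor Nfkbia at 2.33 (SE 0.48), the adhesion molecule Icam1 at 2.40 (SE 0.50), the cytokine receptor chain Csf2ra at 1.50 (SE 0.32) and the inflammatory caspase Casp4 at 1.91 (SE 0.43) in the authors' deposited table. With 7 of 7 calls higher, Fisher's exact test of that list's direction again gave the smallest p that 7 calls allow (adjusted p = 0.0559), a permutation test of its mean log2 fold change did not pass (adjusted p = 0.635), and 9 members passed when adjusted over the list alone. The bound on enrichment, an exact hypergeometric test, passed (adjusted p = 0.0426). The direction of the same 7 calls passed without gene models with an SE over 1, a setting added after the data were seen (Fisher's exact test, adjusted p = 0.0247). That setting removed 61 higher and 0 lower calls from all calls, which by itself lowers this p. The 26 granulocyte and monocyte calls moved the same way in these libraries.

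Granulocyte and monocyte genes formed the largest group of higher calls among the lists. Of 54 genes, 26 were called and all were higher in old (Fisher's exact test, adjusted p = 2.34e-05; bound on enrichment, adjusted p = 8.05e-21). Up to 2.21 calls were due by chance if all gene models were equally likely to be called, and 30 members passed when adjusted over the list alone. The neutrophil genes Retnlg (4.91 to 648 normalized counts, 7.05, SE 1.56), Lcn2 (65.9 to 4918, 6.22, SE 1.50), Cd177 (36.2 to 2621, 6.18, SE 1.53), Mmp8 (6.23, SE 1.55) and Mmp9 (6.19, SE 1.68) had the 5 largest fold changes at a mean of at least 50 in the authors' deposited table. The macrophage glycoprotein Cd68 (3.64, SE 0.62) and the growth factor receptors Csf3r (3.28, SE 0.58) and Csf1r (3.37, SE 0.71) had the smallest adjusted p of the list in the authors' deposited table. The granule genes Ngp and Ltf, named after their values were seen, reached old means of 36140 and 19916 normalized counts from young means of 830 and 276 in the authors' deposited table. Of the 26 called genes, 8 had a young mean of at least 100. In the authors' deposited table the SE of the called genes ran from 0.39 to 1.68, with a median of 1.33, against 0.62 for all higher calls. The list's direction did not pass at an adjusted p limit of 0.01 (17 calls, Fisher's exact test, adjusted p = 0.07) or among calls with a log2 fold change of at least 1 (26 calls, adjusted p = 1.0), where most calls left were higher. Without gene models with an SE over 1, a setting added after the data were seen, 8 of its 26 calls were left and the direction passed (Fisher's exact test, adjusted p = 0.0223).

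**Figure D2:**
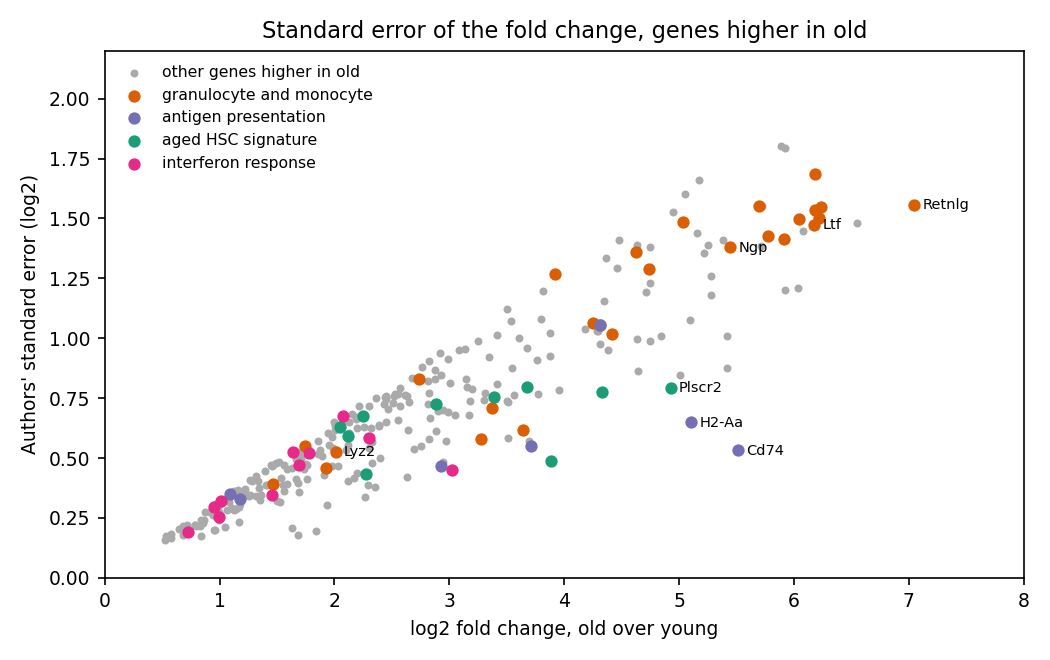
Authors' standard error of the log2 fold change (y axis) against the log2 fold change of old over young (x axis) for gene models called higher in old with both means above 0; colours mark the fixed lists. Granulocyte and monocyte genes reach standard errors up to 1.68, while Cd74 and H2-Aa lie at 0.53 and 0.65.

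In the lists of other cell types the few called markers were all higher in old, as were 62.0% of all calls. Under the bound on enrichment, chance would give 1.23 calls in the mast cell, basophil and eosinophil list and 1.89 in the erythroid list. It would give 2.79 in the lymphoid and plasma cell list and 1.52 in the stroma and endothelium list. The bound passed for none of these lists, so their counts do not show a rise of these cell types. In the mast cell, basophil and eosinophil list 4 of 30 genes were called. Prg3, an eosinophil granule gene, was listed in the authors' deposited table at 0 in young and at 18.7 in old, so no fold is given. Its neighbour Prg2 rose from 24.3 to 1283 (5.72, SE 1.55), Fcer1a from 0.466 to 44.6 (6.55, SE 1.48) and Ear2 by 4.46 (SE 1.29) in the authors' deposited table. The beta globin genes Hbb-bs (2.82, SE 0.82) and Hbb-bt (2.45, SE 0.75) were the 2 called genes of 46 in the erythroid list in the authors' deposited table, and as near-identical copies they may share reads. In the lymphoid and plasma cell list 2 of 68 genes were called, Klrb1c (0.874 to 21.3, 4.64, SE 1.39) and Cd4 (2.38 to 21.1, 3.08, SE 0.95) in the authors' deposited table. A further gene model, named Igh-A_(1g2) in the authors' deposited table and by its symbol an immunoglobulin heavy chain, matched no list symbol and rose from 22 to 837 (5.25, SE 1.39); it was chosen after its values were seen. In the stroma and endothelium list 2 of 37 were called, Lpl (22.8 to 354, 3.96, SE 0.79) and Bgn (13.8 to 104, 2.93, SE 0.85) in the authors' deposited table.

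Of the 93 annotated genes of the oxidative phosphorylation list, 5 were called, and these 5 were lower in old. The called genes fell (Fisher's exact test, adjusted p = 0.0197), and 5 members passed when adjusted over the list alone. That test did not match on expression level. Lower calls had a median young mean of 2195 against 29.1 for higher calls, and all 5 genes had a young mean of at least 100. The passing p may thus reflect their level. The ATP synthase subunit gene Atp5k fell by 1.24 on the log2 scale (SE 0.39, 1230 to 521 normalized counts), the complex II gene Sdhd fell by 0.88 (SE 0.25), the complex I assembly factor Ndufaf2 fell by 0.87 (SE 0.23), and the complex III gene Uqcrc2 fell by 0.68 (SE 0.18, 6764 to 4238) in the authors' deposited table. Up to 3.81 calls were due by chance if all gene models were equally likely to be called, and the bound on enrichment, an exact hypergeometric test, did not pass (adjusted p = 0.862). The list had 0 calls at an adjusted p limit of 0.01 and 1 call with a log2 fold change of at least 1 in size, so its direction could not be tested there. None of these 5 genes passed once all fold changes were recentred as described above. No mitochondrially encoded gene was listed. The 26 granulocyte and monocyte genes were higher in the same old libraries.

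The lower calls with the smallest adjusted p were led by Mtif3, a mitochondrial translation initiation factor (chromosome 5, 146951573 to 146963800, minus strand), with a log2 fold change of -0.72 (SE 0.11, adjusted p = 2.76e-08, 3033 to 1836 normalized counts) in the authors' deposited table. Gtf3a, an RNA polymerase III transcription factor, had -0.79 (SE 0.12, adjusted p = 2.83e-08) in the authors' deposited table. Exons of these 2 neighbouring genes overlap in the annotation, so their reads may be shared. The next were Prodh, proline dehydrogenase (-0.93, SE 0.16), the nucleolar factor Rexo4 (-0.57, SE 0.10), the nuclear pore gene Nup107 (-0.89, SE 0.16), the tubulin Tubb6 (-1.52, SE 0.28), Acat3 (-0.80, SE 0.15), the mitochondrial peptidase Pitrm1 (-0.91, SE 0.18), the mitochondrial fatty acid synthesis enzyme Mecr (-1.02, SE 0.20) and the proteasome-associated deubiquitinase Usp14 (-0.84, SE 0.17) in the authors' deposited table. The annotated span of Acat3 overlaps that of Tcp1, a lower call on the opposite strand that was chosen after its values were seen. With the strand setting not given, reads of Acat3 and Tcp1 may be shared. By the rule for named genes, which leaves out Gm, Rik and AC, BC or AI symbols, the largest falls at a mean of at least 50 were those of Tesc (133 to 19.7 normalized counts, -2.80, SE 0.79), Tubb6, Tmem97 (-1.32, SE 0.39), Atp5k and Ggct (-1.24, SE 0.36) in the authors' deposited table. The 2 gene models of AI506816, chosen after their values were seen, had -1.51 (SE 0.40) and -1.42 (SE 0.43) in the authors' deposited table.

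Among the higher calls with the smallest adjusted p, several belonged to none of the lists. Sepp1, the plasma selenium transporter selenoprotein P, rose from 545 to 1950 normalized counts (1.84, SE 0.20, adjusted p = 5.69e-17) in the authors' deposited table. Sat1, which acetylates polyamines, rose from 219 to 698 (1.68, SE 0.18, adjusted p = 5.69e-17) in the authors' deposited table. The transcript AW112010 rose by 1.63 (SE 0.21) and Ypel3 by 2.26 (SE 0.34) in the authors' deposited table.

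The remaining lists had few calls. Lysosome and autophagy had 3 higher calls, Ctsb (1.17, SE 0.23, 5876 to 13242 normalized counts), Grn (1.04, SE 0.21) and Ctsh (3.18, SE 0.74), and 1 lower, Becn1 (-0.28, SE 0.08) in the authors' deposited table. The unfolded protein and integrated stress list had 2 higher, Nupr1 (2.89, SE 0.72) and Ddit4 (2.57, SE 0.79), and 2 lower, the serine synthesis enzyme Psat1 (-0.91, SE 0.26) and the chaperone Hsp90b1 (-0.59, SE 0.18) in the authors' deposited table. In the p53 and senescence list Xpc was higher (0.85, SE 0.23) and Aen lower (-0.70, SE 0.20) in the authors' deposited table. In lipid and sterol metabolism Alox5ap was higher (1.23, SE 0.35) and Hadha lower (-0.41, SE 0.11) in the authors' deposited table. The 2 redox and metallothionein calls were Aldh1a1 and Gstm1 (1.98, SE 0.47) in the authors' deposited table. Single calls were Jun, higher, among immediate early genes (3.15, SE 0.80), the mitotic kinase gene Plk1, lower, among 88 cell cycle genes (-0.82, SE 0.22), and Hmga1, lower, among chromatin regulators (-0.72, SE 0.22) in the authors' deposited table. The 5 integrin and matrix calls were higher and included Col18a1 (5.39, SE 1.41) in the authors' deposited table, and with 5 of 5 higher Fisher's exact test of direction could not pass (p = 0.162). A permutation test of the list's mean log2 fold change passed (adjusted p = 0.0311), but 3 of the 5 calls stand in another list, among them the neutrophil genes Mmp8 and Mmp9, and 2 calls were left without gene models with an SE over 1. The bound on enrichment, an exact hypergeometric test, did not pass (adjusted p = 1.0). Glycolysis had 0 calls among 26 genes, with 3 listed. The sex-linked, ribosomal protein, mitochondrially encoded and histone lists had no listed member at the authors' adjusted p limit of 0.1.

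**Figure D3:**
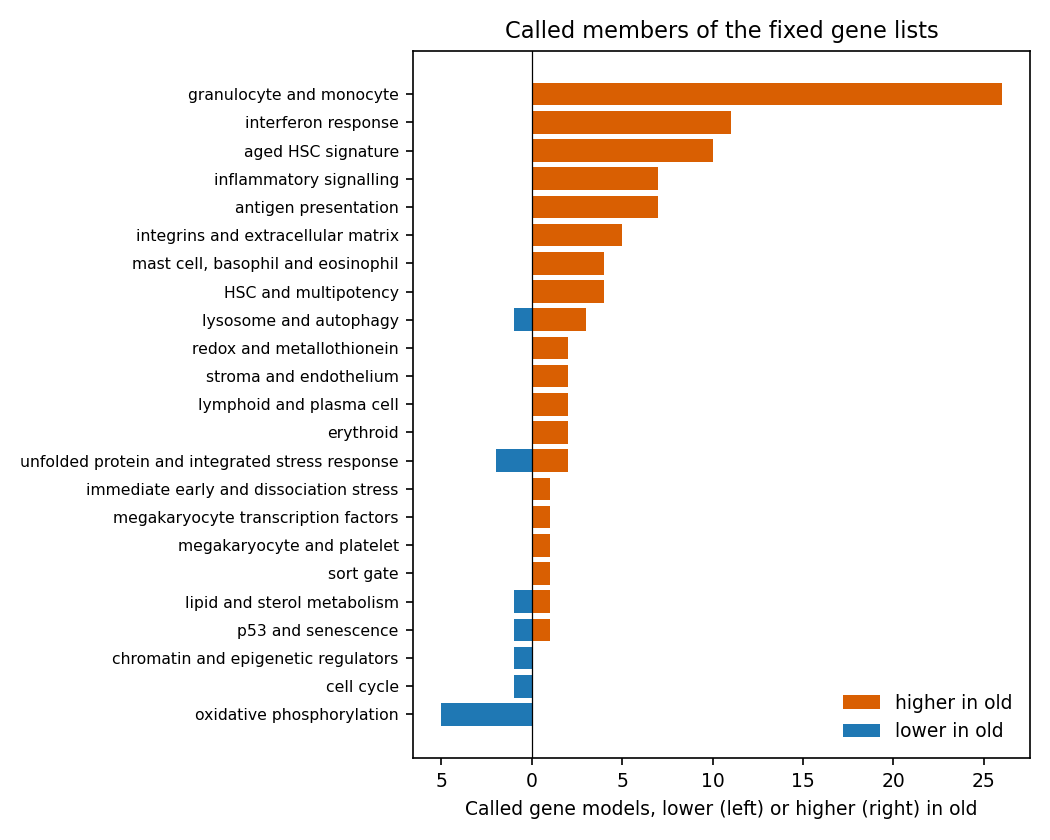
Number of called gene models per fixed list, with bars to the right for genes higher in old and to the left for genes lower in old (x axis, counts); lists without calls are left out. Granulocyte and monocyte genes have 26 higher calls and 0 lower, and oxidative phosphorylation has 5 lower and 0 higher.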

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

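No paired analysis was possible because the deposited values are group means with no value per library. Recentring, the limit on SE, the minimum on the 14-sample mean, the removal of the granulocyte and monocyte list, the merging of neighbours and the bound on enrichment were chosen after the data were seen. For lack of those values no library could be left out and no other normalization or low-count filter could be fitted, and the 2 kinds of old title could not be split. Against 302 higher and 185 lower calls, an adjusted p under 0.01 left 139 and 41, a log2 fold change of at least 1 left 16 lower, an adjusted p under 0.1 gave 337 lower, a mean count of at least 50 left 198 higher, and recentring on the fitted common shift left 5 lower; the cause was the smaller or larger set by construction, and for recentring the shift, fitted to the lower calls. The share of higher calls was 77.2% at 0.01, 94.4% at a log2 fold change of at least 1, 51.7% at a mean of at least 50 and 98.8% after recentring, against 62.0%. The other counts stayed within 1.5 times. The direction test passed for 4 lists. By Fisher's exact test it passed for 0 at an adjusted p under 0.01 and for 0 at a log2 fold change of at least 1, where few lower calls were left to compare with; the granulocyte and monocyte list then had adjusted p = 0.07 and 1.0. It passed for 5 lists at a mean of at least 50, for 6 without gene models with an SE over 1, and for 5 by the permutation test of means, in which the interferon list did not pass. The limits on mean and SE removed higher calls only, which by itself lowers the p of a list with all calls higher. The planned enrichment test over all genes could not be run; its bound passed for 5 lists. Of the 78 named gene models that were called, 29 did not pass at 0.01; Slamf1, not called, passed at 0.1. What depth limits is unknown, since library totals are not given in the sources used here.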

Other observations

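All tests in this part were chosen after the result was seen, and those of standard errors and of scaling were changed again after their first outcome was known; the outcomes of both versions are given. The gene families named first were picked because members stood out among the calls, so a test of them on the same calls is void and only counts are given. Tcp1, Hspa4, Hspa9, Timm44, Samm50, Grpel1, Gstm3, Gstm7, Ndn, Zrsr1, Snurf, Snrpn, Ngp, Ltf, Lyz2, S100a8, S100a9 and Mir5107 were chosen after their values were seen. All 8 called heat shock and chaperonin genes, of 88 annotated, were lower in old, among them Tcp1, a subunit of the cytosolic chaperonin (-0.97, SE 0.24), and Hspa4 (-0.75, SE 0.17) in the authors' deposited table. Reads of Tcp1 may be shared with Acat3, whose annotated span overlaps it. All 6 called mitochondrial import genes, of 31, were lower, including Hspa9 (-0.73, SE 0.17), Timm44 (-0.64, SE 0.15), Samm50 (-0.79, SE 0.22) and Grpel1 (-0.95, SE 0.29) in the authors' deposited table. The mitochondrial ribosome, of 78 genes, and ribosome biogenesis factors, of 56, each had 5 calls, all lower. Proteasome subunits, of 50, and Eif translation initiation factors, of 55 and without Mtif3, had 4 calls each and aminoacyl-tRNA synthetases, of 35, had 2, all lower. None of the genes counted in these families passed as lower when all fold changes were recentred by 0.39 on the log2 scale.

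Among higher calls, 5 of 21 annotated glutathione S-transferases and 5 of 18 cathepsins were called, all higher. In the authors' deposited table Gstm3 had a log2 fold change of 2.99 (SE 0.91) and Gstm7 of 1.89 (SE 0.51); members of the Gstm cluster are close copies and may share reads, which the test of neighbouring calls without exon overlap (permutation p = 0.025) does not settle. Of 26 imprinted genes, 4 gene models were called, all higher in the authors' deposited table: Ndn (37.2 to 420 normalized counts, 3.50, SE 0.74), Zrsr1 (2.75, SE 0.55), and Snurf and Snrpn, which overlap in exons and count as 1 locus.

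The 26 granulocyte and monocyte genes higher in old, of which 3 stand in another list too, include markers of mature cells that the lineage gate should remove. Whether each of the 26 marks only such cells was not tested. The most abundant, Ngp, Ltf and Lyz2, had old means of 36140, 19916 and 13811 normalized counts, from young means of 830, 276 and 3428, in the authors' deposited table. If cells or RNA of that type entered part of the old libraries, the SE of these genes may exceed that of other genes: the medians were 1.41 for 21 genes and 0.99 for 79 others with a log2 fold change of at least 3 (permutation p = 4.00e-05), but because larger folds allow larger SEs among called genes, the test was then changed to compare within bins of fold, where the mean difference was 0.10 (permutation p = 0.0728). If a single outside source brought both these and the Cd74 and MHC class II transcripts, their SEs should be alike. The median was 0.54 for Cd74, H2-Aa, H2-Eb1 and H2-Ab1 against 1.41 for the 21 genes (exact permutation p = 8.70e-04), and against 1.06 once the test was changed to the 11 genes with folds up to that of Cd74 (exact permutation p = 0.105). Each answer thus depends on the matching, which was chosen knowing the first outcome, and the SE may also rest on libraries outside the series. Both sources stay open, as do a change of the progenitors with age and a difference between the kinds of library title, possibly Tomato and GFP fractions, of which the young group has only 1; neither was tested.

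The lower calls were weighed against a scaling difference between groups, which may lower many strongly expressed genes alike. The test of a single factor took gene models as independent, though they share libraries and some may share reads, such as Gtf3a and Mtif3. Its p-values may thus be too small. Under that assumption a single factor as the cause of every lower call is argued against, since their fold changes spread beyond 1 common shift of -0.39 given that only called genes are seen (likelihood-ratio test, n = 185 gene models, p = 1.01e-04). In the first version, without the 5 gene models farthest from the shift, the likelihood-ratio test gave p = 0.0191 (n = 180 gene models). That first version was read as excluding scaling as a whole, which was too broad, so the question of most lower calls was then asked apart: 5 of the lower calls of the authors' deposited table passed as lower after recentring, Mtif3 (from -0.72 to -0.34, SE 0.11), Gtf3a, Prodh, Tubb6 and Mecr, while the shift, fitted to the lower calls themselves, had to end most of the others. For those a common factor stays open, because the uncalled genes that would show the centre of all genes were not analysed here. Dilution by RNA of other cells, a difference between the kinds of library title and a change with age also stay open: dilution would lower megakaryocyte genes, of which 2 were called, Selp and Erg, both higher, too few to decide.

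Neighbouring gene models changed together more often than chance gives. Of 36 pairs of called models with consecutive numbers, 32 had the same direction against 19 by chance, among them all 4 pairs with 1 symbol on both models and all 8 with a model not matched to the annotation, which agreed within 1 SE of the difference and may be the same transcripts counted again. In 6 pairs the exons overlap in GENCODE M21 (Cd74 with Mir5107, Gtf3a with Mtif3, Irgm2 with Igtp, and Snrpn with Snurf among them), and all 6 agreed within 1 SE of the difference, as shared reads would give. Overlapping models without consecutive numbers, such as Tcp1 and Acat3, were not examined. Exon overlap in GENCODE M21 did not cover all pairs. Of 18 pairs without it, 14 had the same direction against 9.49 by chance (permutation p = 0.025), with H2-Ab1 and H2-Aa, S100a8 and S100a9, and Casp4 and Casp12 among them. The annotation behind the counted gene models is not given, so overlap in those models cannot be excluded. Reads placed in 2 copies of a gene and regulation shared by a cluster both stay open for these pairs and were not tested.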
